A study of Mus musculus with 11 samples.

How the data were processed

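Polyadenylated RNA of whole mouse liver was sequenced in 11 libraries from C57BL/6J mice. All mice lacked the LDL receptor (genotype Ldlr-/-). Part of them also carried E06-scFv, a single-chain fragment of the E06 antibody that binds oxidised phospholipids. The mice were fed chow or the AMLN diet, a diet rich in fat, fructose and cholesterol that is used to induce steatohepatitis. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads and fragmented, and the second strand was marked with dUTP. Whether the counting used strand is not given in the sources used here, so reads from a gene and an antisense partner may be mixed.

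The read counts per gene are the authors' own: per the labels, reads were mapped to mm10 with STAR at default parameters, and the deposited counts were made with HOMER over exons, as raw counts with 1 transcript per gene. The versions of STAR and HOMER and the annotation are not given in the sources used here. How reads shared by near-identical copies were treated is not given either, so counts of ribosomal protein genes and their pseudogenes, Tpt1 (a short abundant transcript with processed copies), the Cyp4a, Mup, Saa and haemoglobin genes are uncertain. The deposited tables of each diet also hold the authors' log2 fold changes between genotypes and their p-values, which per the labels came from HOMER's wrapper of DESeq2 within that diet. The deposited TPM and normalised columns, 22 columns in all, were not used here, because the raw counts of the same libraries were used instead.

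Each table lists 24940 genes, of which 23244 were counted on the same transcript in both diets. Comparisons within a diet used all genes of its table, and comparisons across diets used the 23244 genes only. Coordinates are those of the deposited tables, in mm10. GEO's labels gave 4 groups: 3 E06 libraries and 2 Ldlr-/- libraries on AMLN, and 3 of each genotype on chow. The labels do not state that replicates were separate animals, so p-values measure only the spread between these samples. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 30.2), so every library was kept.

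The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling, edgeR's filter on low counts by group and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. The genotypes were compared within each diet in a fit of that diet alone. The interaction and the diet comparisons came from a fit of all 4 groups. Log2 fold changes are E06 minus Ldlr-/-, or AMLN minus chow, and CPM values are TMM-scaled shares of a library's counts, in the usual CPM unit, from the fit they belong to. The Ldlr values given per library are an exception, taken over total counts without TMM scaling. Errors of log2 fold changes are standard errors, which were derived from the fold change and its F statistic. In all, 36 lists of genes (liver pathways, cell type markers and stress responses) were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it, and fry asks only whether the genes of a list move, on balance, in the same direction.

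Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, for a genotype, the 8 genes with the largest rise and the 8 with the largest fall past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups. It took 5 in each direction for a diet and for the interaction, the interaction without the overlap condition. Where fewer than 3 genes passed in a direction, it took the 3 genes with the smallest p. It also took up to 4 members with the smallest p of each list described, and Ldlr and Apoe in every library. The alternatives were DESeq2 1.42.0, size factors of the RLE kind, no filter on low counts, each replicate left out in turn, the replicate number as a block and a fit of all 4 groups. Further alternatives were added after seeing the data: each library's trend on transcript length or GC content removed (lowess, span 0.3), all genes in the diet comparisons, 2 chow libraries left out together, and camera on the interaction.

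The scripts were tested on simulated counts with the real means and library sizes, in which 100 genes were changed by log2 1 and 100 by log2 2. For genotype on AMLN (13708 genes), 34 and 98 were recovered. For genotype on chow (10475 genes), 1 and 56 were recovered, and for the interaction (11967 genes) 0 and 5. For AMLN in Ldlr-/- (11988 genes) 4 and 68 were recovered, and for AMLN in E06 (11880 genes) 6 and 74. Of the unchanged genes, 15, 6, 0, 9 and 5 were called in the same order. These counts were drawn gene by gene without a trend on length, so false calls in the real libraries may be more frequent. A list shifted by log2 1 was called in each of these simulations at the preset correlation. With an estimated correlation it was missed for genotype on AMLN (adjusted p = 0.0532) and for AMLN in E06 (adjusted p = 0.0510), so a list whose call ends there is not shown to be unchanged. An added length trend, linear in log2 length, was removed to a Spearman coefficient across genes of at most 0.03. Before removal this trend alone (Spearman coefficient 0.78) gave 1366 calls for genotype on AMLN. A fold against a group at 0 is given as a bound against 3 counts over that group, which covers counting error only.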

Results

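Liver transcriptomes of mice lacking the LDL receptor, with or without the E06-scFv antibody fragment against oxidised phospholipids, were compared on the AMLN diet and on chow. On AMLN the libraries held 11469373 to 16991841 counts in genes, from 3 samples with E06-scFv (E06) and 2 without it (Ldlr-/-). On chow they held 4185463 to 9940846 counts, with 3 samples of each genotype. Ldlr (mm10 chromosome 9, 21723576 to 21749918), disrupted in all of these mice, was still counted in every library: 353, 154 and 167 CPM in E06 and 149 and 162 CPM in Ldlr-/- on AMLN, and 15.3, 3.11 and 6.57 CPM in E06 and 4.74, 30.9 and 8.57 CPM in Ldlr-/- on chow. These CPM values are shares of each library's total counts, without TMM scaling, so they do not give the fitted change between diets. No group has an intact gene, and which exons were lost is not stated, so Ldlr does not check the labels. Variable-region genes of the antibody were not in the tables, so the transgene was not analysed here. Ldlr did not pass the test between genotypes on AMLN (log2 0.78 ± 0.330, adjusted p = 0.110) or on chow (log2 -0.86 ± 0.576, adjusted p = 1.00). On chow its sign turned to 0.03 without Ldlr-/- chow replicate 2.

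The diets also differed in the make-up of the libraries. Transcripts shorter than 1 kb held 8.30% ± 0.850 (SD, n = 3) of the counts in E06 and 5.58% ± 1.29 (SD, n = 2) in Ldlr-/- on AMLN, against 40.4% ± 12.4 (SD, n = 3) and 36.1% ± 12.9 (SD, n = 3) on chow. Within chow, E06 replicate 1 (26.2%) and Ldlr-/- replicate 2 (21.4%) stood apart from the other 4 libraries (41.7% to 49.0%). The fold changes of genes followed transcript length in every comparison, with a Spearman coefficient across genes of -0.45 for genotype on AMLN, -0.16 for genotype on chow, -0.32 for the interaction, 0.55 for AMLN in Ldlr-/- and 0.40 for AMLN in E06. They also followed GC content. Its coefficient was 0.43 for genotype on AMLN, 0.10 for genotype on chow and 0.33 for the interaction. It was 0.27 for AMLN in Ldlr-/- and 0.43 for AMLN in E06. Each trend was removed alone, never both together. Genes are not independent replicates, so no p is given.

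**Figure D1:**
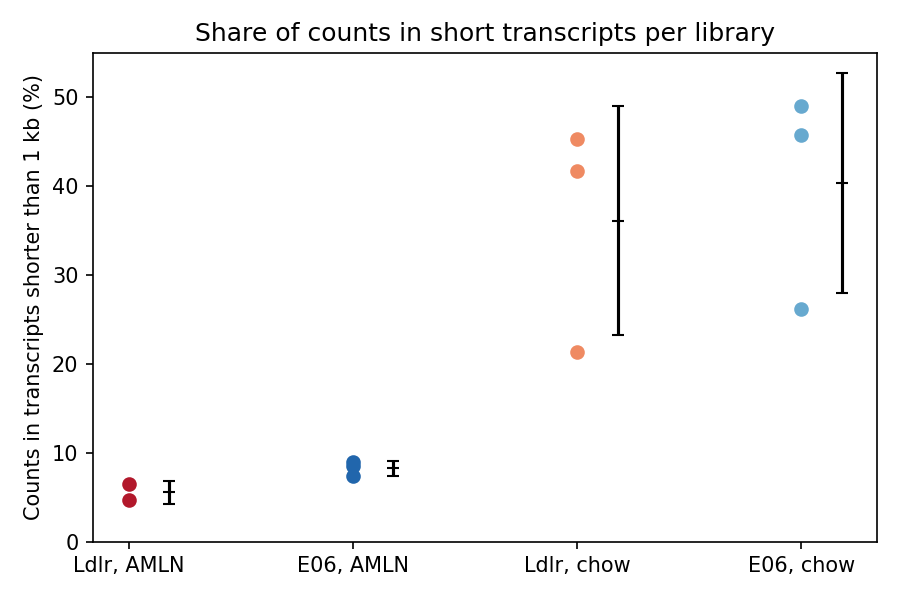
Percentage of each library's counts that fell in transcripts shorter than 1 kb, with 1 point per library and bars for the group mean ± SD. The 5 AMLN libraries lie between 4.66% and 9.04% and the 6 chow libraries between 21.4% and 49.0%.

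The comparison of genotypes on AMLN asked how neutralising oxidised phospholipids changes the liver on a diet that induces steatohepatitis. By camera at its preset correlation, the list of fatty acid oxidation stood higher in E06 livers, and those of macrophages, antigen presentation, matrix and cell division lower. None of these list calls held when the correlation was estimated (smallest adjusted p = 0.698 with an estimated correlation). By fry only the call of fatty acid oxidation held among them (fry adjusted p = 0.0142). Cyp4a14, a microsomal fatty acid omega-hydroxylase, was 11.7-fold higher, at 4780 ± 829 CPM (SD, n = 3) in E06 and 408 ± 215 CPM (SD, n = 2) in Ldlr-/-. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was 4.18-fold lower, at 74.9 ± 17.2 CPM against 313 ± 9.51 CPM. Col3a1, a fibrillar collagen chain, was 5.57-fold lower, at 50.5 ± 36.2 CPM against 282 ± 58.4 CPM.

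Of the 35 tested genes of the fatty acid oxidation list, 19 rose and 16 did not pass, and 23 rose adjusted over the list alone (median log2 0.93, camera adjusted p = 8.51e-08, adjusted p = 0.698 with an estimated correlation). Cyp4a10 rose by log2 2.57 ± 0.231 (adjusted p = 0.000531), Cyp4a14 by 3.55 ± 0.365 (adjusted p = 0.000888), Cyp4a31 by 2.13 ± 0.259 and Acot1, a cytosolic acyl-CoA thioesterase, by 2.28 ± 0.267. These are known targets of PPARalpha. In the lipid droplet list 8 of 19 genes rose, 2 fell and 9 did not pass, with 10 and 2 adjusted over the list alone (median 0.73, camera adjusted p = 0.0127, adjusted p = 0.706 with an estimated correlation). This call also ended once the length trend was removed (median 0.52, camera adjusted p = 0.0805). Fitm1, which partitions lipid into droplets, rose by 2.30 ± 0.285 and the monoacylglycerol lipase Mgll by 1.31 ± 0.210, while Anxa2 fell by 1.63 ± 0.227. Of 23 lipogenesis genes 2 rose, 6 fell and 15 did not pass, with 3 and 7 adjusted over the list alone, and the list was not called (camera adjusted p = 0.400). Its fallen members included Thrsp (log2 -2.31 ± 0.205), the transcription factor Srebf1 (-1.72 ± 0.271) and pyruvate kinase Pklr (-1.56 ± 0.247). Of 21 bile acid genes 6 rose, 2 fell and 13 did not pass (6 and 3 adjusted over the list alone), and this list was not called either (camera adjusted p = 0.150). Cyp8b1, the sterol 12-alpha-hydroxylase, rose by 2.58 ± 0.338 and the nuclear receptor Nr0b2 by 1.98 ± 0.298.

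Of 18 pan-macrophage markers 12 fell and 6 did not pass, with 13 fallen adjusted over the list alone (median log2 -1.10, camera adjusted p = 6.16e-06, adjusted p = 0.706 with an estimated correlation). Examples were Cybb (-2.06 ± 0.231, adjusted p = 0.00119), the cathepsin Ctss (-1.51 ± 0.238), lysozyme Lyz2 (-1.43 ± 0.225) and Aif1 (-1.36 ± 0.212). Of 20 markers of recruited macrophages 11 fell, 2 rose and 7 did not pass, with the same counts adjusted over the list alone (median -1.62, camera adjusted p = 3.65e-05, adjusted p = 0.706 with an estimated correlation). Macrophage elastase Mmp12 (-2.39 ± 0.215), the beta-glucan receptor Clec7a (-2.61 ± 0.275), lipoprotein lipase Lpl (-1.98 ± 0.218) and Cd72 (-1.89 ± 0.226) fell. Among 12 Kupffer cell markers 3 fell, 1 rose and 8 did not pass (4 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.313). Cd5l fell by 1.11 ± 0.207. In the dendritic and antigen presentation list 8 of 14 genes fell and 6 did not pass, with 9 fallen adjusted over the list alone (median -1.33, camera adjusted p = 0.000128, adjusted p = 0.706 with an estimated correlation). Its class II genes H2-Eb1 (-2.25 ± 0.433) and H2-DMb1 (-1.76 ± 0.343) fell. Among genes that sense or take up oxidised lipid, 6 of 20 fell, 4 rose and 10 did not pass, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.340). The scavenger receptor Msr1 fell by 2.07 ± 0.221 and Tlr4 by 1.62 ± 0.257. The list of sinusoidal endothelium, another non-parenchymal cell type, was not called: 2 of 16 rose and 14 did not pass, also adjusted over the list alone (median 0.07, camera adjusted p = 0.665). Signs of carry-over and handling moved in the same comparison: blood and pancreas genes stood higher (median 2.30, camera adjusted p = 0.0350, adjusted p = 0.706 with an estimated correlation), as did immediate early genes, which follow handling of the tissue (median 1.03, camera adjusted p = 0.000473, adjusted p = 0.706 with an estimated correlation). The blood and pancreas call ended without E06 replicate 3 (median 1.05, camera adjusted p = 0.0529) and with the length trend removed (median 1.49, camera adjusted p = 0.185).

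Matrix and fibrosis genes fell in 13 of 36 cases, 1 rose and 22 did not pass, with 19 fallen and 2 risen adjusted over the list alone (median log2 -0.84, camera adjusted p = 3.65e-05, adjusted p = 0.706 with an estimated correlation). Collagens Col3a1 (-2.48 ± 0.440, adjusted p = 0.00474) and Col5a2 (-1.65 ± 0.275) and the matrix glycoprotein Sparc (-1.18 ± 0.210) fell. Of 28 cell cycle genes 9 fell and 19 did not pass, with 10 fallen adjusted over the list alone (median -0.85, camera adjusted p = 3.97e-06, adjusted p = 0.706 with an estimated correlation). Cyclin Ccnd1 fell by 2.19 ± 0.238 and the replicative helicase subunit Mcm6 by 2.00 ± 0.271. Of 12 cholangiocyte markers 4 fell and 8 did not pass, also adjusted over the list alone (median -1.40, camera adjusted p = 0.0063, adjusted p = 0.706 with an estimated correlation). Epcam fell by 2.15 ± 0.504, and this call ended without 1 library (largest adjusted p = 0.0873).

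Short transcripts stood higher in E06, as their share of counts did (8.30% against 5.58%). In the respiratory chain list 18 of 38 genes rose and 20 did not pass, with 19 risen adjusted over the list alone (median log2 0.58, camera adjusted p = 1.36e-06, adjusted p = 0.706 with an estimated correlation). Cox8a rose by 1.68 ± 0.213 and Ndufs7 by 1.67 ± 0.261. In the ribosomal protein list 10 of 35 rose and 25 did not pass, with 11 risen adjusted over the list alone (median 0.44, camera adjusted p = 0.000529, adjusted p = 0.706 with an estimated correlation). Rplp2 rose by 2.81 ± 0.242 and Rps7 by 2.85 ± 0.352. With the length trend removed neither list was called (medians 0.13 and -0.21, camera adjusted p = 0.146 and 0.329). Tpt1 had the largest rise by the naming rule (chromosome 14, 75845256 to 75848303; log2 5.38 ± 0.317, adjusted p = 4.57e-05), followed by the microRNA gene Mir8112 (4.67 ± 0.579). The largest fall was that of Vsig8 (-5.12 ± 0.677, adjusted p = 0.00194). Vsig8 was scarcely counted in E06, at 0.399 and 0.0921 CPM in replicates 1 and 2, so the size of its fall is uncertain. Prune2 (-3.25 ± 0.381), Sytl5 (-3.25 ± 0.591) and the imprinted H19 RNA (-3.17 ± 0.457) were also among the 8 largest falls, and these calls held without each library in turn.

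In all, edgeR called 3112 of 13923 genes, 1615 higher and 1497 lower in E06, and camera called 16 of 36 lists, 10 higher and 6 lower. The authors' deposited table called 3465 genes, of which 3047 were also called here in the same direction. The count fell to 774 without Ldlr-/- replicate 1, 1017 without Ldlr-/- replicate 2 and 1448 without E06 replicate 2, where a lone sample is assumed to vary like the others. It was 268 in a fit of all 4 groups and 1783 with the length trend removed, of which 1499 were called in the same direction as before. With the GC trend removed it was 2265, of which 1731 were called in the same direction as before.

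**Figure D2:**
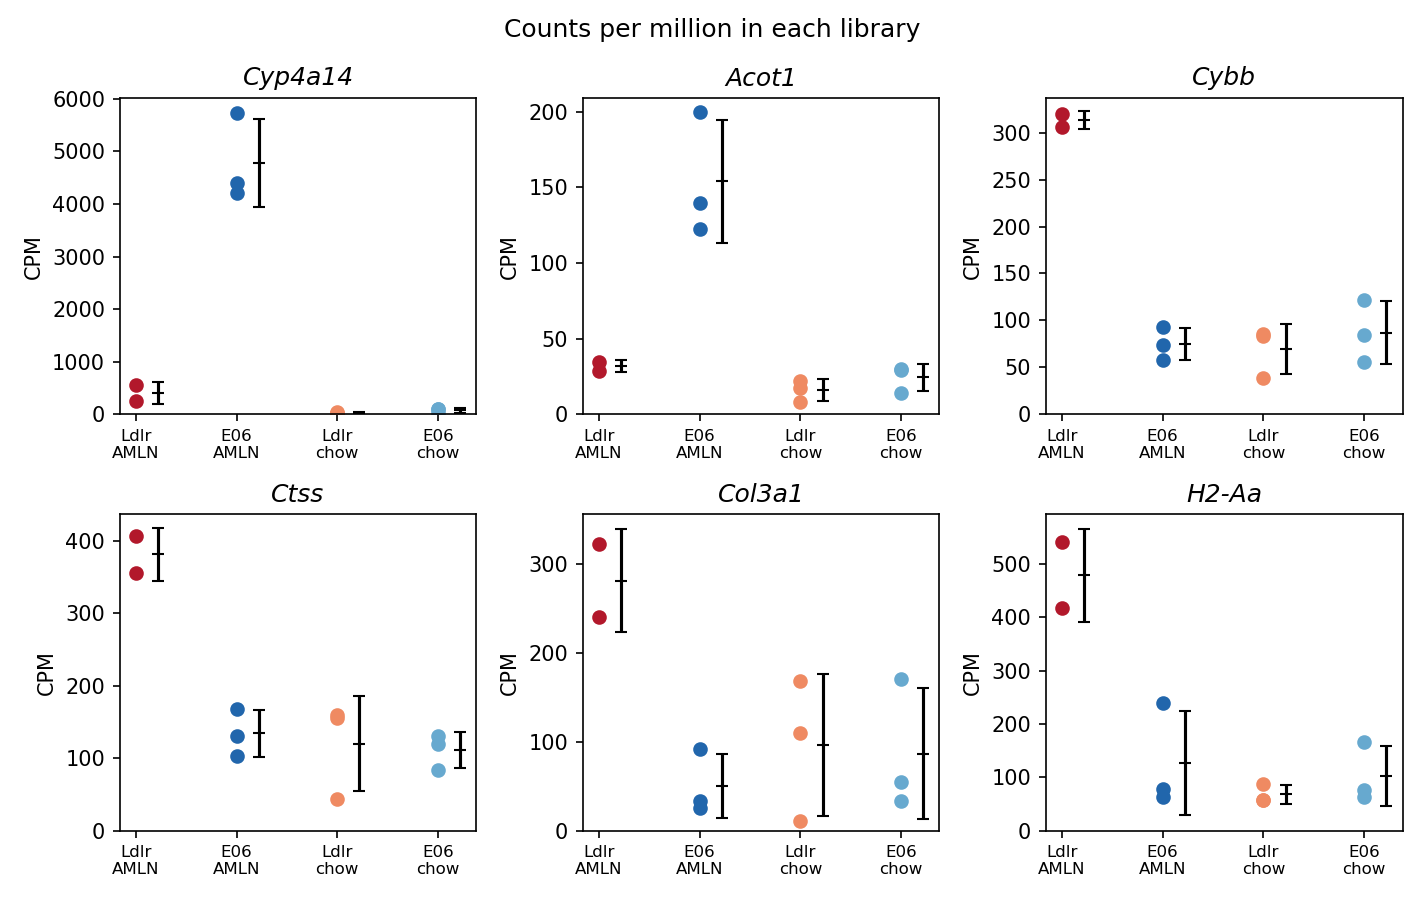
CPM of 6 genes in each library, with each diet scaled separately; points are libraries and bars the mean ± SD of a group (n = 3, or n = 2 for Ldlr-/- on AMLN). On AMLN, Cyp4a14 and Acot1 lie higher in all 3 E06 libraries than in both Ldlr-/- libraries, and Cybb, Ctss, Col3a1 and H2-Aa lie lower; levels on AMLN and chow come from separate scalings.

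**Figure D3:**
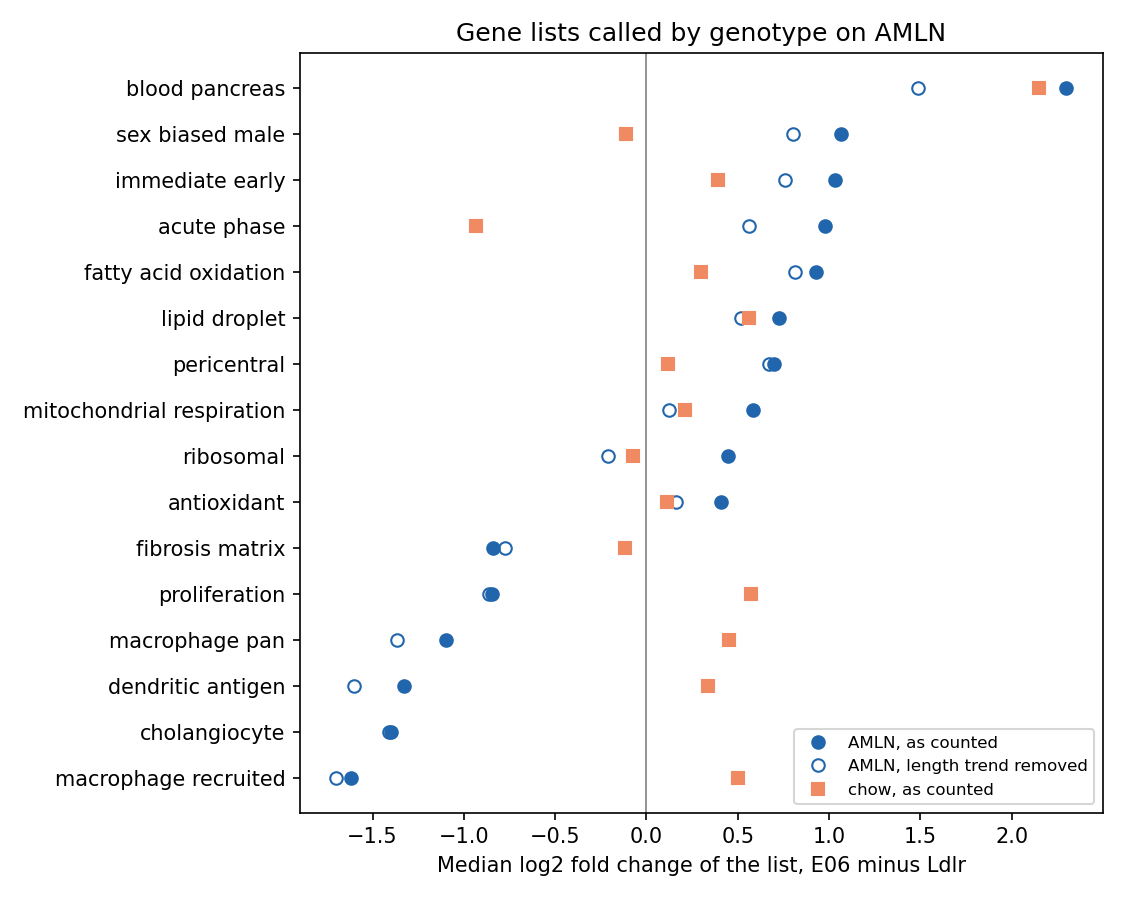
Median log2 fold change, E06 minus Ldlr-/-, of the 16 lists called on AMLN, as counted (filled circles), with the length trend removed (open circles) and on chow (squares; the cholangiocyte list had fewer than 5 tested genes there). The median of the ribosomal list crosses 0 to -0.21 once the length trend is removed.

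The same genotypes on chow showed how far the livers differed without the inducing diet. The acute phase list stood lower in E06 (adjusted p = 0.235 with an estimated correlation): Saa2, a serum amyloid A of the hepatic acute phase, was at 160 ± 42.3 CPM (SD, n = 3) in E06 and 7926 ± 8776 CPM (SD, n = 3) in Ldlr-/-, and Saa1 at 632 ± 138 CPM against 16150 ± 15530 CPM. Cholesterol synthesis genes stood lower as a list (adjusted p = 0.105 with an estimated correlation), with Idi1, the isopentenyl diphosphate isomerase, at 7.05 ± 2.06 CPM against 22.9 ± 4.66 CPM. The lipid droplet list stood higher (adjusted p = 0.235 with an estimated correlation), with the droplet protein gene Plin4 at 5.48 ± 3.29 CPM against 1.31 ± 0.964 CPM. None of these genes passed by edgeR with all libraries.

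By edgeR 0 of 10828 genes passed on chow, with 220 at an unadjusted p under 0.05. DESeq2 called 4: Apoa4 (log2 2.91), Hspa1b (2.99), Pf4 (2.59) and Saa2 (-5.63). The authors' deposited table called 3 genes, Pf4, Apoa4 and Saa2. Without Ldlr-/- replicate 2 edgeR called 3 genes: Saa1 (-5.24), Saa2 (-6.20) and Rpap3 (-2.51), the last chosen for mention after its values were seen. Without this library and E06 replicate 1, the pair with fewer counts in short transcripts, it called 53. The genes with the smallest p by edgeR were Hspa1b (2.95 ± 0.552), Pf4 (2.58 ± 0.488) and Apoa4 (2.88 ± 0.641) among higher ones, and Idi1 (-1.68 ± 0.360), Saa2 (-5.63 ± 1.23) and 3830403N18Rik (-2.68 ± 0.603) among lower ones (adjusted p = 1.00 for each).

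Camera called 18 of 34 lists on chow, 16 higher and 2 lower, none of which had a member past the threshold over all genes tested by edgeR. Other groupings of the same chow libraries gave up to 24 list calls. Of the 10 possible splits, 4 gave at least 18, the real one included. The number of list calls alone therefore does not set the genotypes apart from other groupings. The acute phase list had a median log2 of -0.93 over 24 genes (camera adjusted p = 8.71e-14, adjusted p = 0.235 with an estimated correlation), with 2 fallen adjusted over the list alone. The cholesterol synthesis list had a median of -0.49 over 25 genes (camera adjusted p = 8.82e-09, adjusted p = 0.105 with an estimated correlation), with 1 fallen adjusted over the list alone; Mvd was at -1.54 ± 0.491 and Hmgcr at -0.95 ± 0.332. The lipid droplet list (18 genes) had a median of 0.56 (camera adjusted p = 6.20e-08, adjusted p = 0.235 with an estimated correlation), with Plin4 at 1.92 ± 0.676 and Cidec at 1.28 ± 0.466. The fatty acid oxidation list (33 genes) had a median of 0.30 (camera adjusted p = 1.06e-05, adjusted p = 0.354 with an estimated correlation). The pan-macrophage list (18 genes) had a median of 0.45 (camera adjusted p = 3.64e-07, adjusted p = 0.391 with an estimated correlation), with Itgam at 1.34 ± 0.481 and Cd68 at 0.81 ± 0.409, and lost its call without Ldlr-/- replicate 2 (median 0.15, adjusted p = 0.204). The blood and pancreas list, a sign of carry-over from other tissue, stood higher beside it (7 genes, median 2.15, 4 risen adjusted over the list alone, camera adjusted p = 3.64e-07, adjusted p = 0.235 with an estimated correlation). So did the immediate early list, which follows handling of the tissue (18 genes, median 0.39, camera adjusted p = 3.64e-07, adjusted p = 0.235 with an estimated correlation). The recruited macrophage list (16 genes) had a median of 0.50 (camera adjusted p = 0.00625, adjusted p = 0.547 with an estimated correlation), which lost its call without E06 replicate 3 (median 0.21, adjusted p = 0.759) or Ldlr-/- replicate 2 (median 0.41, adjusted p = 0.393). The T and NK cell list (10 genes) also stood higher (median 0.68, camera adjusted p = 0.000197, adjusted p = 0.235 with an estimated correlation). The neutrophil list (9 genes) had a median of 3.05 (camera adjusted p = 0.000937, adjusted p = 0.507 with an estimated correlation), with 6 risen adjusted over the list alone. S100a8 reached 10945 CPM in E06 replicate 3 against at most 443 CPM in the other 5 libraries, and the list fell to a median of 0.38 without that library (adjusted p = 0.874). The fibrosis list (26 genes) was not called (median -0.12, camera adjusted p = 0.891, direction of the test higher). Removal of the length trend ended the call of the respiratory chain list (median 0.21 before and 0.048 after, camera adjusted p = 0.259) and brought a call of the ribosomal list as lower (median -0.29, camera adjusted p = 4.16e-05, adjusted p = 0.130 with an estimated correlation). In all, 8 of the 18 lists kept their call without each library in turn.

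The interaction asked whether the genotype difference itself differed between diets. By camera at its preset correlation, macrophage, dendritic, cell cycle and matrix lists stood lower in E06 on AMLN relative to the difference on chow, and acute phase and fatty acid oxidation lists higher. All these list calls ended with an estimated correlation (smallest adjusted p = 0.438 with an estimated correlation) and by fry. Tpt1 (log2 5.41 ± 0.668, adjusted p = 0.0136) and Mir8112 (5.42 ± 0.749, adjusted p = 0.0166) had a more positive genotype difference on AMLN, but Mir8112 lost its call with the length trend removed (4.14, adjusted p = 0.167) or the GC trend removed. Gcnt1, a glycosyltransferase that forms core O-glycan branches, had a more negative one (-4.38 ± 0.597, adjusted p = 0.0166). Among genes that did not pass, those with the smallest p were Tm7sf2 (2.69 ± 0.487, adjusted p = 0.105), Prune2 (-4.26 ± 0.695, adjusted p = 0.0761) and Gbp2 (-2.40 ± 0.425, adjusted p = 0.105).

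Camera, run on the interaction only after the data were seen, called 14 of 36 lists, 6 higher and 8 lower, and none with an estimated correlation or by fry (smallest adjusted p = 0.438 with an estimated correlation). The pan-macrophage list had a median log2 of -1.37 over 16 genes (camera adjusted p = 6.91e-09, adjusted p = 0.438 with an estimated correlation), with 8 lower adjusted over the list alone, and the recruited macrophage list -1.56 over 18 genes (camera adjusted p = 3.95e-07, adjusted p = 0.438 with an estimated correlation), with 8 lower adjusted over the list alone. The acute phase list had a median of 1.84 over 23 genes, 17 of them higher adjusted over the list alone (camera adjusted p = 6.91e-09, adjusted p = 0.438 with an estimated correlation). Of 12460 genes edgeR called 3, with 1636 at an unadjusted p under 0.05, while DESeq2 called 307. Each of the 3 lost its call without E06 replicate 2, E06 replicate 3, Ldlr-/- replicate 1 or Ldlr-/- replicate 2 on AMLN, where edgeR called 0 genes (1101, 1206, 953 and 1060 at an unadjusted p under 0.05), and the count was 28 without Ldlr-/- replicate 2 on chow.

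AMLN feeding of Ldlr-/- mice was compared with chow to show the response to the diet itself. The list of cholesterol synthesis stood lower on AMLN (adjusted p = 0.240 with an estimated correlation): Idi1 stood at 0.493 ± 0.264 CPM (SD, n = 2) on AMLN and 33.1 ± 7.30 CPM (SD, n = 3) on chow, and the squalene epoxidase Sqle at 4.53 ± 0.374 against 83.4 ± 21.4 CPM. Single genes that stood higher included the collagens Col4a2 (38.2-fold) and Col1a1 (30.8-fold), the droplet protein gene Plin4 (25.5-fold) and Gpnmb (16.0-fold), a marker of lipid-laden macrophages. The matrix, lipid droplet and recruited macrophage lists to which they belong were not called as counted (camera adjusted p = 0.0642, 0.0777 and 0.527), while the lipid droplet and recruited macrophage lists were called higher once the length trend was removed (camera adjusted p = 0.000109 and 0.0287, adjusted p = 0.802 and 0.895 with an estimated correlation). The ribosomal protein list stood lower (adjusted p = 0.287 with an estimated correlation), with Rps8 at 8.32 ± 2.28 against 742 ± 329 CPM. Diet coincides with the share of counts in short transcripts (at most 9.04% on AMLN, at least 21.4% on chow) and with the deposited table, so the diet and a difference in library preparation cannot be told apart.

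Of 24 cholesterol synthesis genes 19 fell, 1 rose and 4 did not pass in Ldlr-/-, with 22 fallen and 1 risen adjusted over the list alone (median log2 -1.75, camera adjusted p = 6.90e-07, adjusted p = 0.240 with an estimated correlation). Idi1 fell by 6.05 ± 0.523, Sqle by 4.20 ± 0.475 and Msmo1 by 3.67 ± 0.357 (adjusted p = 2.51e-05, 3.29e-05 and 2.98e-05). All 33 tested ribosomal protein genes fell, also adjusted over the list alone (median -4.57, camera adjusted p = 2.88e-19, adjusted p = 0.287 with an estimated correlation). The respiratory chain list had 23 fallen, 1 risen and 11 that did not pass, also adjusted over the list alone (median -2.07, camera adjusted p = 5.66e-07, adjusted p = 0.851 with an estimated correlation), with Ndufs4 at -4.45 ± 0.565 and Atp5o at -4.17 ± 0.480. With the length trend removed 9 of these genes rose and 10 fell, and the list was not called (median -0.36, camera adjusted p = 0.559). Of 22 lipogenesis genes 10 rose, 1 fell and 11 did not pass, also adjusted over the list alone (median 1.03, camera adjusted p = 0.0414, adjusted p = 0.851 with an estimated correlation). Fads2 rose by 3.25 ± 0.470 and Pklr by 2.76 ± 0.397. Of 10 cholangiocyte markers 8 rose and 2 did not pass, with 9 risen adjusted over the list alone (median 2.93, camera adjusted p = 0.0268, adjusted p = 0.851 with an estimated correlation); Epcam rose by 3.18 ± 0.798. Of 20 male-biased liver genes 13 fell, 4 rose and 3 did not pass, with 13 and 5 adjusted over the list alone (median -3.10, camera adjusted p = 0.0268, adjusted p = 0.851 with an estimated correlation), and of 8 blood and pancreas genes 6 fell and 2 did not pass, also adjusted over the list alone (median -3.71, camera adjusted p = 0.0268, adjusted p = 0.851 with an estimated correlation). Both lists lost their calls without Ldlr-/- replicate 2 on AMLN (adjusted p = 0.0652 and 0.0606), and the blood and pancreas list also without Ldlr-/- replicate 2 on chow (adjusted p = 0.0882). Once the length trend was removed, the calls also ended for the blood and pancreas list (median -1.22, camera adjusted p = 0.912), the male-biased list (median -2.70, camera adjusted p = 0.0773) and the lipogenesis list (median 0.54, camera adjusted p = 0.100). The lipogenesis and cholangiocyte lists lost their calls without Ldlr-/- replicate 2 on AMLN (adjusted p = 0.0775 and 0.0510), and the cholangiocyte list also without Ldlr-/- replicate 2 on chow (adjusted p = 0.0766).

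Other lists were not called although many members passed. In the matrix and fibrosis list 13 of 31 rose, 3 fell and 15 did not pass, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.0642), and Col4a2 rose by 5.26 ± 0.488 and Col1a1 by 4.94 ± 0.759. In the recruited macrophage list 8 of 18 rose, 4 fell and 6 did not pass, with 9 and 4 adjusted over the list alone (camera adjusted p = 0.527). Once the length trend was removed, 11 of them rose and none fell (median 1.26, camera adjusted p = 0.0287, adjusted p = 0.895 with an estimated correlation). So did 12 lipid droplet genes (median 2.25, camera adjusted p = 0.000109, adjusted p = 0.802 with an estimated correlation), 10 pan-macrophage markers (median 1.74, camera adjusted p = 0.000109, adjusted p = 0.895 with an estimated correlation) and 6 dendritic and antigen presentation genes (median 1.66, camera adjusted p = 0.0448, adjusted p = 0.895 with an estimated correlation). Fatty acid oxidation was also called only then, with 13 risen and 1 fallen (median 0.68, camera adjusted p = 0.0226, adjusted p = 0.895 with an estimated correlation). Gpnmb rose by 4.00 ± 0.701 and Trem2 by 2.56 ± 0.466. Invariant chain Cd74 rose by 3.75 ± 0.577, Plin4 by 4.67 ± 0.618, Cidec by 2.81 ± 0.424 and Mki67 by 3.76 ± 0.653. The largest rises included Shc2 (6.57 ± 1.23), Pls1 (6.52 ± 1.10) and Rab11fip4 (5.94 ± 0.963), and the largest falls Mup12 (-9.70 ± 1.63) and Tpt1 (-9.55 ± 0.699). Gm12718 and Rps15a-ps6, at 0 in both AMLN libraries, were at least 368-fold and at least 211-fold lower. Ldlr itself rose by 2.37 ± 0.551 and Apoe by 1.68 ± 0.442.

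By edgeR 6677 of 12460 genes passed in Ldlr-/-, 3552 higher and 3125 lower on AMLN, and camera called 7 of 36 lists, 2 higher and 5 lower. The median of all genes lay at log2 0.21 with TMM and 0.10 with RLE scaling in Ldlr-/- and at 0.20 and 0.09 in E06, so changes are relative to that shift. Without Ldlr-/- replicate 2 on AMLN 4183 genes were called, and 3 lists. With the length trend removed, 3956 of the 6677 genes were called in the same direction.

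The response to AMLN in E06 mice was described in the same way. The cholesterol synthesis list again stood lower on AMLN (adjusted p = 0.398 with an estimated correlation), with Idi1 at 0.204 ± 0.120 CPM (SD, n = 3) against 10.2 ± 2.89 CPM (SD, n = 3) and Cyp51, the lanosterol demethylase, at 10.3 ± 2.99 against 146 ± 27.5 CPM. The fatty acid oxidation list stood higher (adjusted p = 0.883 with an estimated correlation), with Cyp4a10 at 1776 ± 210 CPM against 31.3 ± 9.47 CPM. The T and NK cell list stood lower (adjusted p = 0.883 with an estimated correlation), with the CD3 chain gene Cd3d at 1.05 ± 0.576 CPM against 39.3 ± 22.8 CPM.

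Of 24 cholesterol synthesis genes 17 fell, 2 rose and 5 did not pass in E06, with 19 and 2 adjusted over the list alone (median log2 -1.31, camera adjusted p = 5.02e-05, adjusted p = 0.398 with an estimated correlation). Idi1 fell by 5.62 ± 0.484, Cyp51 by 3.82 ± 0.359 and Sqle by 4.34 ± 0.409 (adjusted p = 1.01e-05 for each). Of 33 fatty acid oxidation genes 19 rose, 1 fell and 13 did not pass, also adjusted over the list alone (median 1.28, camera adjusted p = 0.00372, adjusted p = 0.883 with an estimated correlation). Cyp4a10 rose by 5.83 ± 0.431, Cyp4a31 by 4.77 ± 0.445 and the peroxisomal thiolase Acaa1b by 4.56 ± 0.586. Of 17 T and NK cell genes 10 fell and 7 did not pass, also adjusted over the list alone (median -2.50, camera adjusted p = 0.0371, adjusted p = 0.883 with an estimated correlation). Cd3d fell by 5.25 ± 0.596 and Cd2 by 3.70 ± 0.480, and the list lost its call without E06 chow replicate 1 (adjusted p = 0.0879) or replicate 3 (adjusted p = 0.0570). It also lost its call with the length trend removed (median -1.30, camera adjusted p = 0.150). Of 33 ribosomal protein genes 32 fell and 1 did not pass, also adjusted over the list alone (median -4.21, camera adjusted p = 1.49e-16, adjusted p = 0.398 with an estimated correlation), and of 35 respiratory chain genes 20 fell and 15 did not pass, also adjusted over the list alone (median -1.60, camera adjusted p = 6.89e-05, adjusted p = 0.883 with an estimated correlation). With the length trend removed 11 respiratory chain genes rose and 10 fell, and that list was not called (median -0.14, camera adjusted p = 0.856). The matrix list was not called (9 rose, 6 fell and 16 did not pass, also adjusted over the list alone; camera adjusted p = 0.842), although Col4a2 rose by 3.36 ± 0.431. Recruited macrophage genes Clec7a (-3.83 ± 0.537) and Ms4a7 (-4.33 ± 0.619) fell, while their list (2 rose, 8 fell and 8 did not pass; 2 and 9 adjusted over the list alone) was not called (camera adjusted p = 0.131). The lipid droplet list (10 rose, median 1.72, camera adjusted p = 0.00558, adjusted p = 0.976 with an estimated correlation) and the acute phase list (14 rose, median 1.01, camera adjusted p = 0.0133, adjusted p = 0.976 with an estimated correlation) were called only once the length trend was removed. The neutrophil genes S100a8 (-7.77 ± 1.61) and S100a9 (-7.85 ± 1.56) fell, with the highest chow level in E06 replicate 3.

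By edgeR 7126 of 12460 genes passed in E06, 3853 higher and 3273 lower on AMLN, and camera called 5 of 36 lists, 1 higher and 4 lower. The rises of Gm16982, Klhl3 and Scara3, all at 0 on chow, were at least 15.9-fold, 12.9-fold and 12.5-fold. Phospho1 rose by 7.40 ± 0.743 and Irs2, the insulin receptor substrate, by 6.21 ± 0.968. Camera called 8 lists without E06 replicate 1 on AMLN.

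The relation of the genotype difference on AMLN to the diet difference in Ldlr-/- asked whether genes moved by the diet stood the other way in E06. Across 12460 genes the log2 fold changes of both comparisons had a Pearson r of -0.34 and a covariance of -0.58. Both use the Ldlr-/- AMLN libraries, which alone gives a negative relation. In 20 simulated sets of unchanged groups r was -0.57 (-0.59 to -0.55) and the covariance -0.14. The observed covariance differed from the simulated one by -0.43. The simulated counts were drawn gene by gene without a length trend, with the mean and spread of each gene taken over all 4 groups. The difference of -0.43 and the narrow range are therefore not calibrated to the Ldlr-/- AMLN libraries themselves. Of the genes higher on AMLN in Ldlr-/-, 600 were lower in E06 on AMLN and 259 were higher, where independent lists of these sizes would share 375 and 437 of the 12178 genes tested in both. Of the genes lower on AMLN, 616 were higher and 116 were lower in E06, where independent lists would share 360 and 310. These overlaps use the shared controls, from which part of the excess may come. After the data were seen, each comparison was given a different Ldlr-/- AMLN library, which left r of -0.14 (covariance -0.28) with replicate 1 for the genotype and -0.41 (covariance -0.72) with replicate 2. With the length trend removed r was -0.16 and the covariance -0.20 with shared controls, and with separate controls r was 0.051 (covariance 0.081) and -0.22 (covariance -0.28). The sign of the relation therefore depended on which library served which comparison once length was accounted for. With 1 library left out r ranged from -0.45 to -0.28.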

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

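The tests of transcript length, of the share of cells other than hepatocytes and of library preparation were chosen only after the results were seen, as was the list test of the interaction, while the test of depth was set before. Results are given here because the genotype difference differed between diets by the interaction test. At the level of genes this held for Tpt1 (log2 5.41), Mir8112 (5.42) and Gcnt1 (-4.38), of which Mir8112 lost its call with the length trend removed (adjusted p = 0.167) or the GC trend removed. Among lists it held only by camera at its preset correlation, with none called by fry and none when the correlation was estimated (smallest adjusted p = 0.438 with an estimated correlation). The medians of log2 were lower for cell cycle genes (-1.77), pan-macrophage markers (-1.37), recruited macrophage markers (-1.56), dendritic and antigen presentation genes (-1.87), matrix and fibrosis genes (-0.97), cholangiocyte markers (-1.21), T and NK cell markers (-0.72) and inflammatory signals (-0.38). They were higher for acute phase genes (1.84), male-biased genes (1.03), fatty acid oxidation (0.75), ribosomal proteins (0.64), pericentral genes (0.51) and the respiratory chain (0.39). Once the length trend was removed the calls of ribosomal proteins (median 0.18, camera adjusted p = 0.371) and the respiratory chain (median 0.067, camera adjusted p = 0.706) ended, while the Kupffer cell list was called lower only then (median -0.73, camera adjusted p = 0.0142, adjusted p = 0.688 with an estimated correlation). With 1 library left out, 5 of the 14 lists lost their call: male-biased genes (median 0.63, adjusted p = 0.605 without Ldlr-/- replicate 2 on AMLN), inflammatory signals (largest adjusted p = 0.296), the respiratory chain (0.256), pericentral genes (0.154) and ribosomal proteins (0.0801). No gene kept its call without each AMLN library in turn.

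On AMLN, camera at its preset correlation called the pan-macrophage, recruited macrophage, antigen presentation and matrix lists lower in E06. None of these calls held when the correlation was estimated (adjusted p = 0.706 with an estimated correlation) or by fry. Camera did not call the Kupffer cell list (camera adjusted p = 0.313). Removing the length trend left the differences of mean log2 scores in place: -1.34 ± 0.304 (SE) for pan-macrophage markers (-1.05 before), -1.36 ± 0.276 for recruited macrophages (-1.05 before), -1.56 ± 0.455 for antigen presentation (-1.37 before) and -0.82 ± 0.347 for matrix (-0.96 before). For the macrophage and antigen presentation lists this argues against the length trend as their whole cause. The matrix difference is less clear of 0 against its standard error, with 3 and 2 libraries, so it does not decide. A lower share of all cells other than hepatocytes would move endothelial and macrophage markers alike, but they moved apart by 1.18 ± 0.107, which argues against it. A change in the number or state of macrophages, in carry-over or handling of the tissue, and any other difference between the 3 E06 and 2 Ldlr-/- samples, stays open.

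On AMLN 10 of 35 ribosomal protein genes and 18 of 38 respiratory chain genes rose in E06, and the calls of both lists ended when the correlation was estimated (adjusted p = 0.706 with an estimated correlation). The ribosomal difference went from 0.51 to -0.075 ± 0.0655 (SE) once the length trend was removed. The list thus rose no more than other transcripts of its length, and its rise may be technical. The trend was fitted to these same libraries, so a real rise shared by short transcripts would be removed as well. The removal therefore cannot tell a technical from a real rise. The respiratory chain difference went from 0.64 to 0.16 ± 0.0531. That is still above 0 by more than 2 standard errors, but the list was no longer called, so a smaller biological part cannot be told apart from the trend.

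Of 33 ribosomal protein genes 33 fell on AMLN in Ldlr-/- and 32 in E06. As counted, both list calls ended when the correlation was estimated (adjusted p = 0.287 and 0.398 with an estimated correlation) but held by fry (fry adjusted p = 1.96e-05 and 2.88e-05). Once the length trend was removed, both calls also held with an estimated correlation (adjusted p = 0.0212 and 0.0418). After the length trend was removed, differences stayed at -2.19 ± 0.0872 (SE) in Ldlr-/- (-4.37 before) and -1.99 ± 0.0621 in E06 (-3.75 before). The removed trend was smoothed (span 0.3), and the trend of the simulated check was linear in log2 length. A steeper loss of the shortest transcripts may therefore remain, so these differences do not exclude length as the whole cause. With all libraries thinned to the shallowest, the medians were -4.64 and -4.23, and all 31 tested genes fell in each genotype. Random thinning keeps the expected share of each gene, so these medians could hardly move and do not decide on depth. A library preparation that follows diet cannot be told apart from the diet, since the lowest chow share of counts in short transcripts exceeds the highest AMLN share by 12.4 percentage points and no diet holds libraries of both kinds. A response of the liver to AMLN therefore stays open and untested.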

How the results depend on the processing

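The settings without a length or GC trend, with all genes, or without both chow libraries with fewer short-transcript counts were chosen only after the results were seen, as were all settings of the interaction's lists and the relation's length, left-out and separate-control settings. For genes chosen by the naming rule 1912 values kept direction and side of the threshold, 144 lost the call, 35 gained it and 1 turned; for lists the counts were 628, 179, 0 and 4. Where a count below moved, the cause was not tested. Genotype on AMLN called 3112 genes, 774 to 4426 with 1 library left out (774 without Ldlr-/- replicate 1, 1017 without Ldlr-/- replicate 2, 1448 without E06 replicate 2, fewer samples), 268 in the fit of all 4 groups and 1783 without the length trend. Genotype on chow called 0 by edgeR (220 at an unadjusted p under 0.05), 4 by DESeq2, 16 without the filter, 0 to 3 with 1 library left out (3 without Ldlr-/- replicate 2) and 53 without both chow libraries. The interaction called 3, but 307 by DESeq2, 292 without the filter, 7 without the length trend, 155 without both chow libraries and 0 to 28 with 1 library left out (28 without Ldlr-/- chow replicate 2, 11 without E06 chow replicate 1, 7 without E06 chow replicate 2 or Ldlr-/- chow replicate 3, 5 without E06 AMLN replicate 1, 2 without E06 chow replicate 3, 1 without Ldlr-/- chow replicate 1, 0 without any other AMLN library; 953 to 1206 at an unadjusted p under 0.05). AMLN in Ldlr-/- called 6677, 4183 (without Ldlr-/- AMLN replicate 2) to 7146 with 1 library left out. With an estimated correlation 0 lists were called in each of the 5 comparisons as counted. With the length trend removed, the ribosomal list passed at an estimated correlation for AMLN in Ldlr-/- (adjusted p = 0.0212) and in E06 (adjusted p = 0.0418). By fry 3 lists were called for genotype on AMLN, 1 on chow and 0 for the interaction. Genotype on AMLN kept fatty acid oxidation, the respiratory chain and antioxidant genes (fry adjusted p = 0.0142, 0.0358 and 0.00365), and chow kept cholesterol synthesis (0.0189). Fry called 10 lists for AMLN in Ldlr-/- and 12 for AMLN in E06, which held all 7 and all 5 lists called by camera. Genotype on AMLN called 10 lists without the length trend. AMLN in Ldlr-/- called 3 lists without the GC trend, 3 without both chow libraries and 3 to 12 with 1 library left out (3 without AMLN replicate 2, 12 without chow replicate 3); AMLN in E06 called 4 to 8 (8 without AMLN replicate 1). The relation was -0.44 over called genes, -0.16 without the length trend and -0.45 to -0.28 with 1 library left out (-0.45 without Ldlr-/- AMLN replicate 1). With separate controls it was -0.14 and -0.41, and without the length trend also 0.051, which turned, and -0.22. Of values that turned, the ribosomal list on AMLN had a median of -0.21 without the length trend. On chow with 1 library left out, Ldlr ranged from -1.37 to 0.029 (without Ldlr-/- replicate 2), the Kupffer cell list from -0.073 (without Ldlr-/- replicate 2) to 0.49, and the respiratory chain list from -0.045 (without E06 replicate 2) to 0.41. The Kupffer cell list was at -0.10 without both chow libraries. The inflammatory signal list had a median of -0.087 without E06 replicate 3, although its test kept its direction. On chow the simulated test, which keeps the real depth and spread, recovered 1 of 100 genes changed by log2 1; which of them limits it was not tested. Thinned to the shallowest library, genotype on AMLN still called 2529 genes.

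Same-numbered samples of the genotypes did not consistently deviate together (correlations across genes of -0.44, -0.36 and 0.37 on chow, -0.25 and -0.02 on AMLN). The largest value on chow, 0.65, joined E06 replicate 1 and Ldlr-/- replicate 2, the pair with fewer counts in short transcripts. Deviations from a mean of so few libraries mirror each other, so these values give no sign of pairing but cannot exclude it. With the replicate number as a block 1864 genes were called for genotype on AMLN and 0 for the interaction (849 at an unadjusted p under 0.05), and not every sample correlated best with its own number.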

Other observations

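In this part only the removal of the length trend was chosen after the results were seen. Further lists were called for genotype on AMLN. Of 24 acute phase genes 7 rose and 17 did not pass, with 12 risen adjusted over the list alone (median log2 0.98, camera adjusted p = 0.0063, adjusted p = 0.731 with an estimated correlation), and Lbp, which presents endotoxin, rose by 1.87 ± 0.272. The call of this list ended once the length trend was removed (2 rose, median 0.56, camera adjusted p = 0.0559). Of 24 immediate early genes, which follow handling of the tissue, 9 rose and 15 did not pass, with 11 risen adjusted over the list alone (median 1.03, camera adjusted p = 0.000473, adjusted p = 0.706 with an estimated correlation); Zfp36 rose by 2.30 ± 0.259 and Jund by 1.60 ± 0.257. Of 20 male-biased liver genes 7 rose and 13 did not pass, with 9 risen adjusted over the list alone (median 1.07, camera adjusted p = 0.00221, adjusted p = 0.731 with an estimated correlation), among them Elovl3 (4.08 ± 0.547) and Cyp4a12b (2.06 ± 0.276), but the call ended without Ldlr-/- replicate 2 (median 0.58, adjusted p = 0.197). Of 16 pericentral genes 5 rose and 11 did not pass, with 7 risen adjusted over the list alone (median 0.70, camera adjusted p = 0.00661, adjusted p = 0.706 with an estimated correlation), including Oat (1.45 ± 0.246). Of 31 antioxidant genes 9 rose, 2 fell and 20 did not pass, with 10 and 2 adjusted over the list alone (median 0.41, camera adjusted p = 0.0248, adjusted p = 0.706 with an estimated correlation), and metallothionein Mt1 rose by 2.68 ± 0.419. With the length trend removed 5 of them rose and 4 fell, and the list was not called (median 0.16, camera adjusted p = 0.369). Of 9 genes of blood and pancreas, which mark carry-over, 6 rose and 3 did not pass, also adjusted over the list alone (median 2.30, camera adjusted p = 0.0350, adjusted p = 0.706 with an estimated correlation). Haemoglobin Hba-a1 stood at 61.6 ± 65.3 CPM (SD, n = 3) in E06 and 7.22 ± 2.18 CPM (SD, n = 2) in Ldlr-/-, and the list lost its call without E06 replicate 3 (median 1.05, adjusted p = 0.0529) or Ldlr-/- replicate 2 (median 2.26, adjusted p = 0.117), and with the length trend removed (median 1.49, camera adjusted p = 0.185).

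Lists that were not called still held genes that changed. The stress hormone Gdf15 rose by 2.83 ± 0.311 in E06 on AMLN, while the chemokines Ccl6 (-1.82 ± 0.214) and Cxcl14 (-2.02 ± 0.295) fell. In the inflammatory signal list 6 of 32 genes rose, 6 fell and 20 did not pass, also adjusted over the list alone (camera adjusted p = 0.656; its median lies below 0 and its mean above). The unfolded protein list had 7 risen and 19 that did not pass, also adjusted over the list alone (camera adjusted p = 0.0743), and the neutrophil list 4 risen and 8 that did not pass, with 6 risen adjusted over the list alone (camera adjusted p = 0.113). T and NK cell, B and plasma cell, interferon, circadian, cholesterol synthesis, xenobiotic and periportal lists were not called either (camera adjusted p = 0.423, 0.313, 0.736, 0.433, 0.433, 0.195 and 0.768).

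Only 10 splits exist for 3 against 3 samples, too few for a share under 0.05. On chow the real split gave 0 genes by edgeR (220 at an unadjusted p under 0.05, 4 genes by DESeq2) and the highest other split 0, so all 10 gave as many, and camera called 18 lists against 24 in the highest other split, with 4 splits at least as high. For AMLN in E06 the real split gave 7126 genes and the highest other 0, so 1 split was as high, while camera called 5 lists against 18 in the highest other split, with 9 splits at least as high. Every other split of the E06 libraries still holds 2 libraries of a diet against 1, so its lists may carry the diet difference itself.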
